A study of Danio rerio with 45 samples.

How the data were processed

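Zebrafish (Danio rerio) embryos at 3 stages were sliced along the animal-vegetal axis and the RNA of each slice was sequenced (TOMO-seq). The stages were 1 hour post fertilisation (hpf; about 4 cells), 2 hpf (about 64 cells) and 3 hpf (about 1000 cells). Section A is the most animal of the 5 sections and section E the most vegetal. Per the labels' protocols, RNA was extracted with TRI reagent and lithium chloride, ribosomal RNA was removed with a depletion kit, and strand-specific libraries were made from equal RNA amounts. Every value is therefore a share of the RNA of its section, not an amount per embryo.

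The deposited count table holds whole-number read counts for 12670 genes in 40 libraries, per the file headers and the values. The 5 sections of the third replicate at 2 hpf have no column and are not analysed here, so 2 hpf has n = 2 and the other stages n = 3. Each listed gene has at least 60 counts over the 40 libraries, so low genes were removed before deposit by a rule that is not stated. The deposited normalised signal table equals the counts divided by 1 size factor per library, with a relative spread of that ratio of at most 6.9e-17. The deposited stage totals are a score made by adding the rounded normalised values of the 5 sections, with a largest difference of 0 from that sum. Per the submitters' processing notes, fastp 0.23.4, STAR 2.7.11, HTSeq 2.0.4, DESeq2 and genome build GRCz11 were used. The notes state neither the roles of the tools nor the gene annotation. The reference gene table at hand is of another assembly, so no coordinates are given and symbols stand as deposited. A total of 1082 rows carry a symbol with a copy number after it, and 764 symbols have more than 1 row. Reads of near-identical copies can be split among such rows, so values of genes such as fer, tdrd1, dda1_1 and zdhhc24_2 are uncertain.

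Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with TMM factors, its standard filter on low counts and Benjamini-Hochberg adjustment at 0.05. Within each stage the replicate number was a block, since the labels give sections of the same stage and number as 1 biological replicate. Deviations from the section means correlated between sections of 1 number with a median of 0.66 at 1 hpf and 0.589 at 3 hpf but 0.0998 at 2 hpf. The correlations at 2 hpf ran from 0.0127 to 0.859, so the block has little support for some pairs of sections there. One test asked for any difference among the 5 sections and others compared each section with A. A change of localisation was tested as the stage by section (E minus A) interaction over all 40 libraries, with a block for each of the 8 embryo samples. Stages were compared on the sums of the 5 section libraries of each embryo sample, without a block. Such a sum weights sections by depth and not by their RNA content. Log2 fold changes are printed with their standard error (SE), and CPM as mean and SD. CPM are counts divided by the library's total and by its TMM factor in that fit, times 1e6. P-values measure the spread between these samples.

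For the stage comparison, the replicate numbers were checked for pairing. Embryo sums with the same number at 1 and 3 hpf deviated together from their stage means, with correlations across genes of 0.73, 0.709 and 0.911. The labels do not say what a shared number stands for, so the pairing comes from this check. Numbers 1 and 2 were not distinguishable from each other, with crossed correlations of 0.724 and 0.748. The result with the replicate block therefore stands beside the comparison of 3 with 1 hpf.

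A total of 20 gene lists were fixed before the data were examined. They were germ plasm, piRNA pathway, vegetal oocyte RNAs, animal pole oocyte RNAs, maternal regulators of genome activation, first zygotic genes, oocyte and egg coat genes, mitochondrial genome, ribosomal proteins, cell cycle, DNA replication, histone supply, Wnt signalling, Nodal and BMP signalling, mRNA decay and translational control, yolk syncytial layer, enveloping layer, maternal liver and blood, ovarian follicle cells, and stress response. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. A symbol with several rows, such as tdrkh, tdrd1 or grhl3, entered its list by the row with the highest mean count. Its other rows did not enter the list tests. The tests, their designs, the alternatives and the rule for named genes were also chosen before the data were examined. The rule took, in each comparison, the genes with the largest change in each direction. They had to pass the test, differ the same way in every replicate, reach 10 CPM in the higher group and have a descriptive symbol. At 2 hpf it was applied to the 2 replicates present. Up to 4 called members of each list and 12 fixed genes were added. Of those fixed genes, wnt8a was not in the count table. Some genes that the rule took are not reported here. Where a gene had 0 counts in a group, a fold was computed against a floor of 3 counts over the group, from library totals without TMM factors, which covers counting error only.

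The tests were tried on simulated counts with 200 changed genes. Each gene had 1 mean before the change and no difference between replicates. The shares with the replicate block therefore do not show what the block does on these data. At 12597 genes, the comparison of E with A at 1 hpf recovered 68% of genes changed 2-fold and 92% of those changed 4-fold, with 8 false calls. At 2 hpf (12593 genes) these were 45%, 74% and 7, and at 3 hpf (12625 genes) 70%, 85% and 5. The change of the E-to-A difference from 1 to 3 hpf (12668 genes) gave 34%, 74% and 2. Comparing 3 with 1 hpf (12667 genes) gave 48%, 78% and 4, and with the replicate block 81%, 98% and 25. The shares for 2 against 1 hpf were 40% and 75%, with 3 false calls, and for 3 against 2 hpf 48% and 71%, with 2 false calls. With 1 list shifted among 20, camera called that list and 1 unshifted list.

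Alternatives were RLE size factors, library totals only, no filter on low counts, DESeq2 1.42.0, the other choice of block, all 40 libraries in 1 fit, equal weight of sections, the deposited stage totals, and leaving out each replicate in turn. Equal weight of sections and the deposited stage totals were tested with limma on log2 values, so the test changed together with the summing. Chosen after seeing the data were the summing of symbol copies and the omission of single libraries of low depth or of unusual profile. Adjustments for the side of each library on the first principal component were also run for 2 hpf and for the stages. Their results were seen and gave more calls, but they define groups from the measured values, so they are not reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.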

Results

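RNA was measured in 40 section libraries of 8 zebrafish embryo samples: 3 at 1 hpf, 2 at 2 hpf and 3 at 3 hpf, each divided into sections A (animal) to E (vegetal). Total counts per library ranged from 1466522 to 6428496 at 1 hpf, from 1466266 to 6566549 at 2 hpf and from 1355607 to 5398317 at 3 hpf. Between 12077 and 12597 of the 12670 genes were detected per library. Section E was the shallowest at 3 hpf, with 1355607 to 2327972 counts against 4316597 to 5398317 in section A. The lowest depth of each stage was that of section A of 1 hpf replicate 1, section E of 2 hpf replicate 2 and section E of 3 hpf replicate 1. The first principal component held 41.6% of the variance and set replicate 3 of 1 and 3 hpf, with sections A, B and E of 2 hpf replicate 2, apart from the other libraries.

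Part of this difference lay between rows of the same symbol. For espl1, which encodes separase, the row espl1_1 had 110 ± 16.1 CPM in the 10 libraries of replicate 3 at 1 and 3 hpf and 0.208 ± 0.26 CPM in the 20 of replicates 1 and 2 (SD), and espl1_2 had 0.456 ± 0.406 and 117 ± 11 CPM. The spindle gene aspm gave 190 ± 38.1 and 37.7 ± 16.9 CPM, and aspm_1 gave 0.054 ± 0.088 and 130 ± 46.5 CPM. These examples were chosen after their values were seen. In 60 of 745 symbols with exactly 2 rows the rows differed in opposite directions by more than 1 log2 unit.

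**Figure D1:**
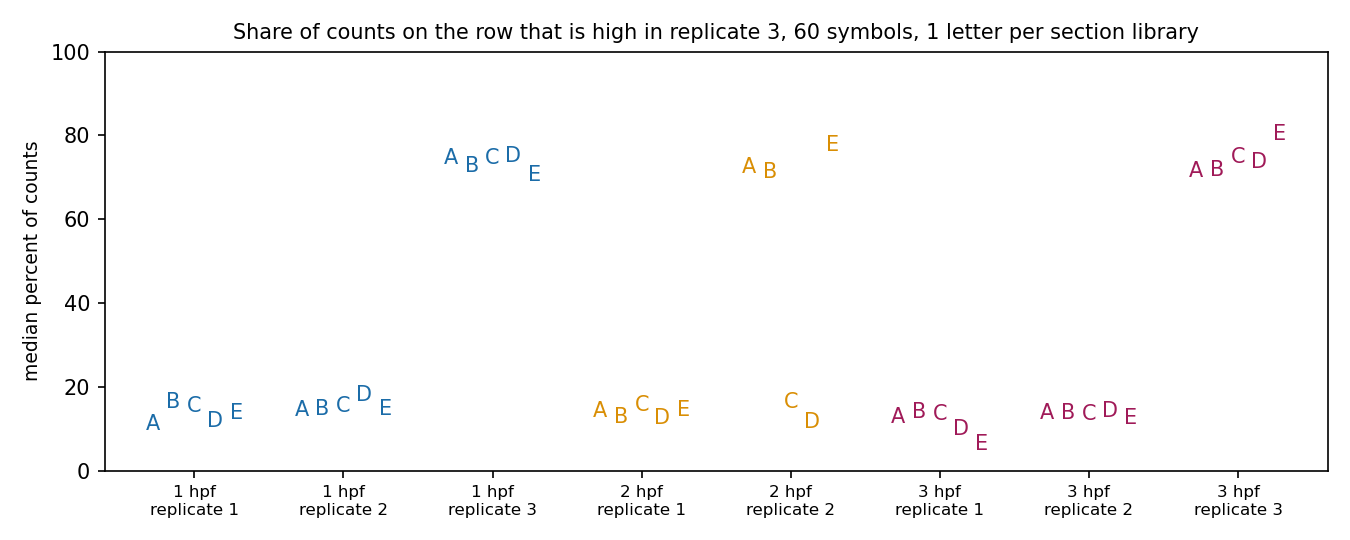
Median percent of counts, over 60 symbols picked at 1 and 3 hpf, on the row that was high in replicate 3, with 1 letter per section library and replicates along the horizontal axis. Sections A, B and E of 2 hpf replicate 2 lay between 71.3% and 77.6%, and its sections C and D at 16.4% and 11.6%.

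The comparison of sections within a stage asks which transcripts lie toward either end of the embryo. At 1 hpf, dazl, which encodes a germ cell RNA-binding protein, reached 3158 ± 399 CPM in section E and 55.1 ± 25.6 CPM in section A (SD, n = 3). Its log2 fold change was 6.0 ± 0.24 (SE; edgeR adjusted p = 3.14e-14). The dorsal determinant hwa (log2 fold change 5.84 ± 0.28), the kinesin linker sybu (5.18 ± 0.23) and grip2a, a scaffold gene needed for dorsal specification (5.01 ± 0.16), were also higher in E. So were vrtn, the histone mRNA binding gene slbp2, the ubiquitin ligase gene trim36 and fer, with changes from 4.39 to 4.52. At the other end, exd2, which encodes an exonuclease, fell from 283 ± 14.5 CPM in A to 18.8 ± 2.60 CPM in E (log2 fold change -3.90 ± 0.12; edgeR adjusted p = 1.09e-15). The phosphatase subunit gene ppp2r3b (-4.17 ± 0.23), the mitotic regulator fbxo5 (-3.56 ± 0.12) and foxh1, a transcription factor of Nodal signalling (-2.95 ± 0.13), were also higher in A. All of these differed the same way in 3 of 3 replicates.

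Of 12597 genes tested at 1 hpf, 1451 differed among the 5 sections, 851 were higher in E than in A and 799 higher in A. Section E held the highest mean for 54% of the 1451 genes and the lowest for 43.6%. With library totals as the scaling, the median of all genes moved to -0.14 (log2) and the split became 684 higher and 1699 lower in E. Compared with A, section D had 214 genes higher and 243 lower, and section C had 2 higher and 0 lower (325 at an unadjusted p under 0.05). Section B had 0 genes different from A with edgeR and 463 at an unadjusted p under 0.05. Without the replicate block the 3 counts were 796, 566 and 414, and all 980 E-to-A calls were among those made with it. Without replicate 2 the number higher in A was 480, and without replicate 3 it was 527.

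**Figure D2:**
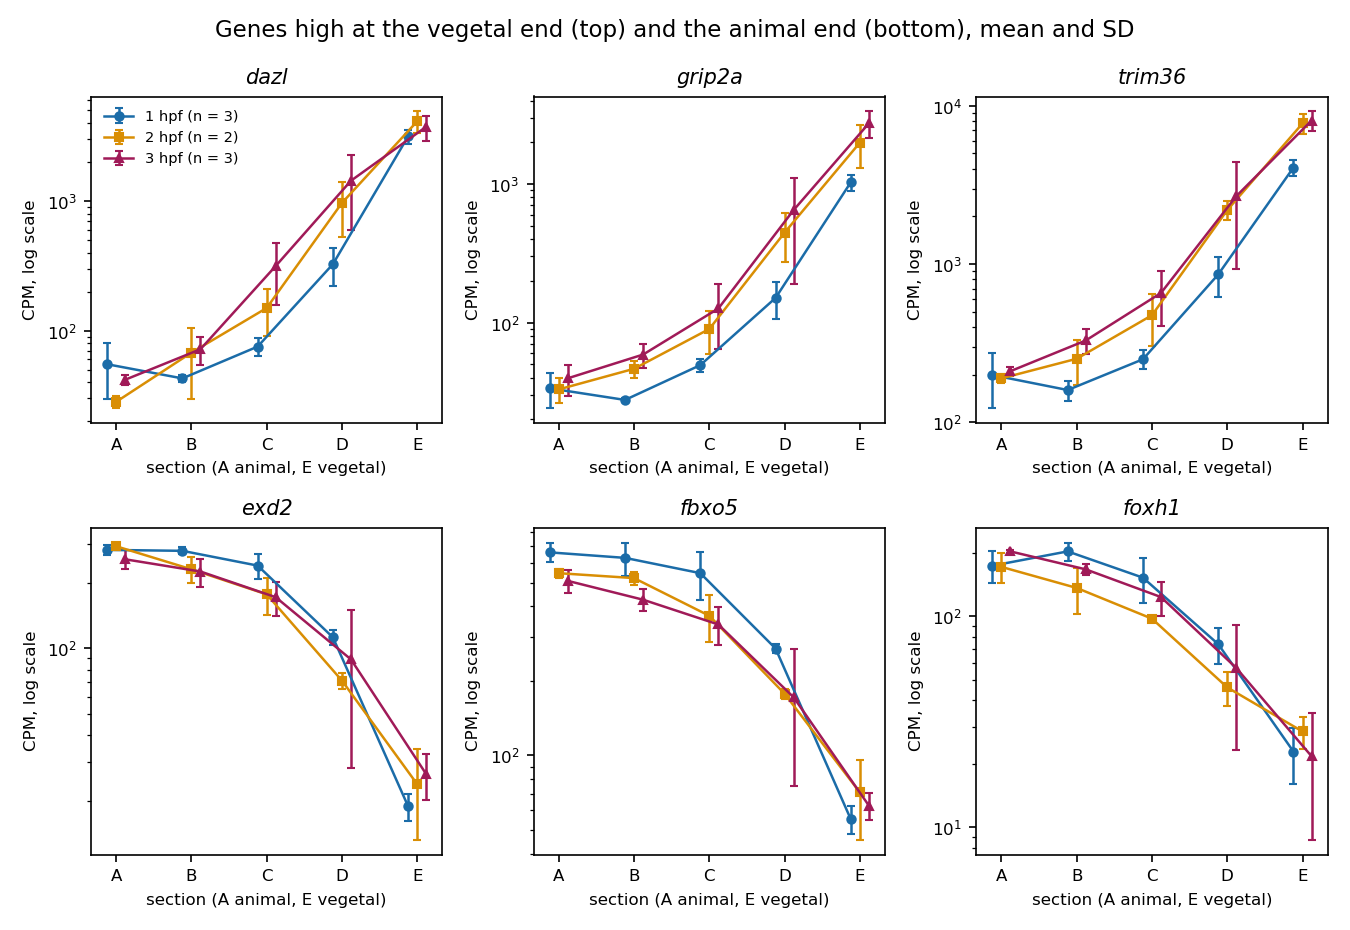
Mean CPM (log axis) with SD by section for dazl, grip2a and trim36 (top) and exd2, fbxo5 and foxh1 (bottom) at 1, 2 and 3 hpf (n = 3, 2 and 3). The mean of dazl at 1 hpf was 55.1 CPM in section A and 3158 CPM in section E, and that of exd2 was 283 and 18.8 CPM.

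The lists describe which kinds of genes these were at 1 hpf. Of 11 germ plasm genes, 8 were higher in E and 0 lower, both over all genes tested and adjusted over the list alone. Among them were hook2 (3.07 ± 0.18), dnd1 (1.71 ± 0.15) and the helicase gene ddx4 (0.99 ± 0.20). The germ plasm organiser buc (0.15 ± 0.09) and nanos3 (0.16 ± 0.17) did not pass. Of 10 vegetal oocyte RNAs, 8 were higher in E and 1 lower (macf1a, -0.67), as they were over the list alone. Of 7 animal pole oocyte RNAs, 6 were higher in A, including pou5f3, a regulator of genome activation (-1.50 ± 0.11), and the cyclin gene ccnb1 (-0.68 ± 0.06). Over the list alone 6 were higher in A and 1 in E, and gdf3 was 0.20 ± 0.07. The camera adjusted p was 7.04e-08, 1.85e-11 and 3.87e-07 for these 3 lists. With an estimated correlation the adjusted p was 0.16, 0.0675 and 0.0675. DNA replication genes had 10 of 26 higher in A and 1 higher in E (11 and 1 over the list alone), among them ticrr (-0.74 ± 0.08) and orc3 (-0.58 ± 0.13). Cell cycle genes had 6 of 21 higher in A and 1 in E, such as aurka (-1.30 ± 0.09). Their camera adjusted p was 0.00134 and 0.0174, and 0.0753 for both with an estimated correlation.

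The other lists at 1 hpf gave no camera call. The piRNA pathway had 1 member higher in E (tdrkh_1, 1.27 ± 0.14) and 5 higher in A, among them tdrd1 (-1.47 ± 0.12) and piwil2 (-0.74 ± 0.09), of 11 (camera adjusted p = 0.0642). Of 15 Wnt signalling genes, 3 were higher in E, led by lef1 (3.72 ± 0.17), and 4 in A, led by axin1 (-1.71 ± 0.11; camera adjusted p = 0.67). Of 8 maternal regulators, 2 were higher in E, eomesa (1.29 ± 0.14) and nanog (0.22 ± 0.06), and 3 in A, which included sox19b (-0.20 ± 0.06; camera adjusted p = 0.176). Of 17 Nodal and BMP signalling genes, 2 were higher in E and 4 in A (camera adjusted p = 0.976), and of 25 mRNA decay genes 3 each (camera adjusted p = 0.67). Histone supply had 2 of 13 higher in E (camera adjusted p = 0.273), with slbp at 2.23 ± 0.08. Oocyte and egg coat genes had 2 of 13 (0.439 by camera), ribosomal proteins 2 of 68 (0.67) and stress response genes 1 of 4, atf3 (0.495). First zygotic genes (4 tested, camera adjusted p = 0.976) and ovarian follicle cells (3 tested, 0.841) had 0 called members by edgeR. No member of the mitochondrial genome, yolk syncytial layer, or maternal liver and blood lists was in the count table.

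At 2 hpf (n = 2), dazl stood at 4121 ± 796 CPM in E and 28.2 ± 3.14 CPM in A (SD), a log2 fold change of 7.24 ± 0.26 (SE; edgeR adjusted p = 4.08e-07). The largest other differences toward E were those of birc2 (6.72 ± 0.96), an inhibitor of cell death, grip2a (5.92 ± 0.28), sybu (5.51 ± 0.17), trim36 (5.34 ± 0.22), vrtn (5.15 ± 0.19), the phosphatase gene ctdsplb (5.01 ± 0.15) and hwa (4.95 ± 0.19). Toward A they were ppp2r3b (-3.83 ± 0.53), ccdc102a (-3.64 ± 0.28), exd2 (-3.55 ± 0.18), clstn1 (-3.38 ± 0.27), traip (-3.03 ± 0.43), itpkcb (-2.95 ± 0.17), fbxo5 (-2.92 ± 0.18) and abca3b (-2.79 ± 0.26). Each differed the same way in 2 of 2 replicates. Of 12593 genes, 817 differed among sections, 645 were higher in E and 613 higher in A. Section C had 34 genes higher and 34 lower than A (1248 at an unadjusted p under 0.05). Section D had 279 and 211, and section B 0 with edgeR (335 at an unadjusted p under 0.05). In replicate 2, sections C and D differed in profile from A, so the counts for C and D can hold more than position. With library totals the median moved to -0.14 and the split was 538 higher and 1003 lower.

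In the lists at 2 hpf, 8 of 11 germ plasm genes were higher in E (9 over the list alone), with dnd1 at 2.68 ± 0.17 and ddx4 at 1.71 ± 0.23. Of the vegetal oocyte RNAs 8 of 10 were higher in E and 1 lower. Of the animal pole RNAs 6 of 7 were higher in A. The camera adjusted p was 2.44e-10, 2.44e-10 and 2.17e-05, and with an estimated correlation the adjusted p was 0.186, 0.186 and 0.251. Of 68 ribosomal protein genes 7 were higher in E and 0 lower (13 over the list alone), among them rps7 (1.16 ± 0.31). Their camera adjusted p of 5.2e-08 became an adjusted p of 0.512 with an estimated correlation. Maternal regulators had 1 of 8 higher in E and 3 in A (camera adjusted p = 0.0359, and 0.251 with an estimated correlation), with ep300b at -0.85 ± 0.11. DNA replication had 4 of 26 higher in A (0.0319 by camera, and an adjusted p of 0.287 with an estimated correlation). Sections C and D of replicate 2 differed in profile from its other sections, and without them the counts were 1175, 864 and 855. Without the replicate block they were 566, 556 and 443. In a fit without replicate 1 only replicate 2 is left, so position and the profile of its sections C and D cannot be told apart. The number differing among sections was 2067 with all 40 libraries in 1 fit, which keeps those sections. Without section E of replicate 2, a library of low depth, they were 521, 428 and 314.

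At 3 hpf, dazl was again the gene with the largest change toward E among those named, at 3744 ± 819 CPM in E and 41.8 ± 3.71 CPM in A (SD, n = 3; log2 fold change 6.51 ± 0.36 SE; edgeR adjusted p = 7.16e-12). It was followed by grip2a (6.16 ± 0.28), sybu (5.56 ± 0.25), trim36 (5.26 ± 0.23), hwa (5.25 ± 0.27), vrtn (5.22 ± 0.22), the RNA-binding protein gene celf1 (4.87 ± 0.22) and ctdsplb (4.72 ± 0.21). Toward A, the largest changes included precursors of miR-430, a microRNA family that clears maternal transcripts. The gene dre-mir-430a-13 had 214 counts over the 3 libraries of section A and 0 in E, at least 28.7-fold higher in A, and dre-mir-430a-4 had 167 and 0, at least 22.4-fold higher. Near-identical copies of this family share reads, so values of single copies are uncertain. The transcription factor genes her5 (at least 24.8-fold), vox (at least 18.1-fold) and irx7 (at least 15-fold) likewise had 0 counts in E. For klf17, also a transcription factor gene, A stood at 24.9 ± 14.9 CPM and E at 0.871 ± 1.11 CPM (log2 fold change -4.64 ± 0.75; edgeR adjusted p = 8.39e-05). The genes ppp2r3b (-4.25 ± 0.31), adam8a (-4.01 ± 0.36) and lrmp (-3.65 ± 0.29) were also higher in A.

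Of 12625 genes at 3 hpf, 1514 differed among sections, 1023 were higher in E and 946 in A. Section D had 490 genes higher and 366 lower than A, section C 110 and 25, and section B 0 with edgeR (150 at an unadjusted p under 0.05). With library totals the median moved to -0.22 and the split was 721 higher and 2346 lower. Without the replicate block 849 genes differed among sections, 703 were higher in E and 458 in A, all 1161 of them among the calls with it, and without replicate 2 the first of these counts was 953.

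**Figure D3:**
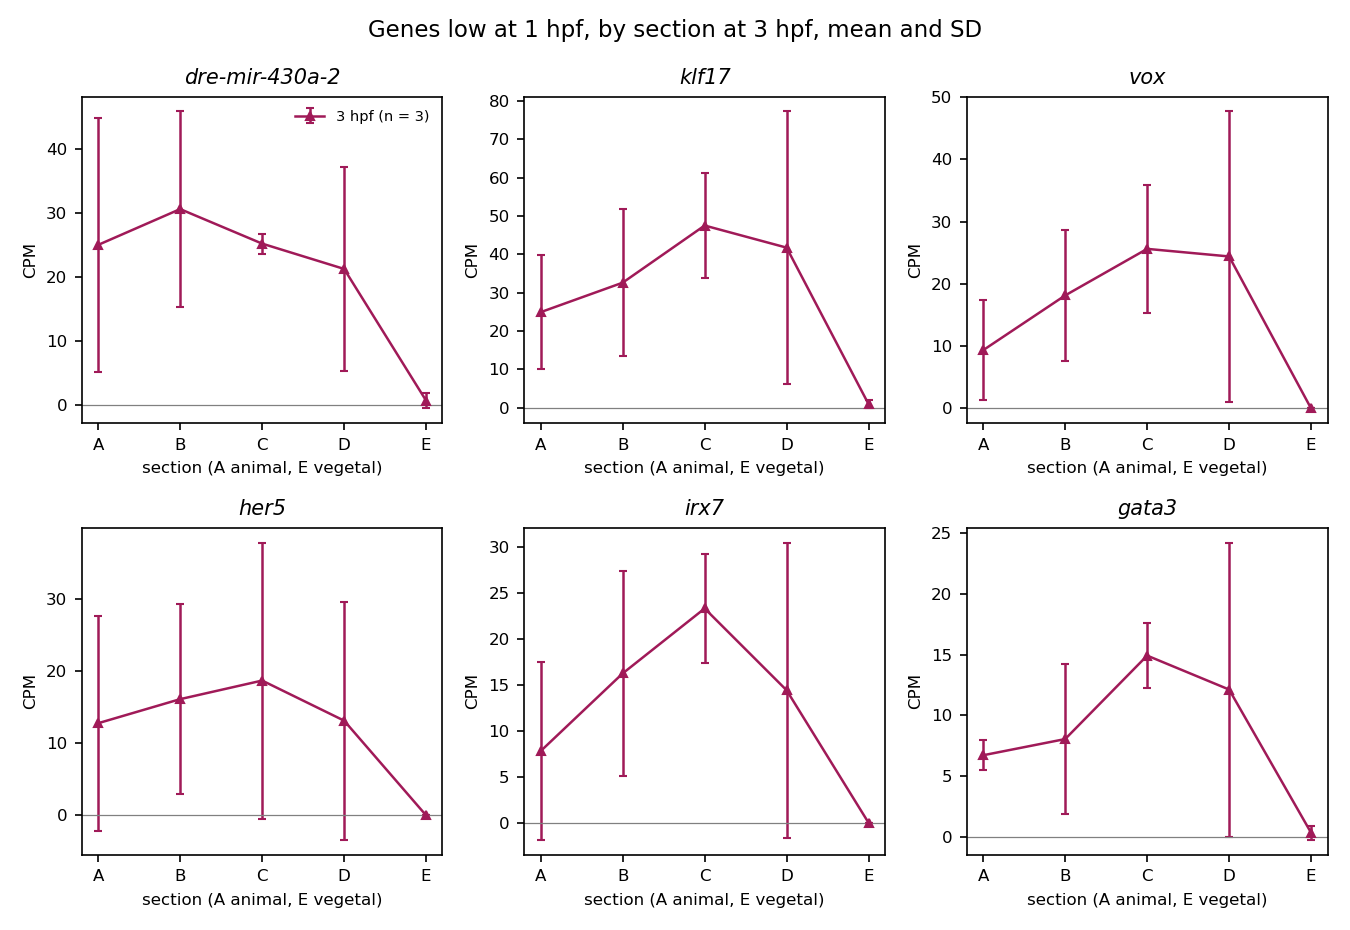
Mean CPM with SD (n = 3) by section at 3 hpf for dre-mir-430a-2, klf17, vox, her5, irx7 and gata3. Means of klf17 were 24.9 CPM in section A and 47.5 CPM in section C, and 0.871 CPM in section E.

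Among the lists at 3 hpf, 7 of 13 first zygotic genes were higher in A and 0 in E, the same over the list alone, among them vox, klf17, irx7, gadd45bb (86 counts in A and 0 in E, at least 11.5-fold) and nnr (55 and 0, at least 7.38-fold). Their camera adjusted p of 0.0109 became an adjusted p of 0.599 with an estimated correlation. Higher in A here means against E only, not highest in A. By library totals, vox had 9.56 CPM in A and 18.5 CPM over all sections. For klf17 these values were 26 and 34.8, for irx7 7.94 and 15, and for gadd45bb 6.09 and 11.6. Only nnr, of those named, was not lower in A (3.9 and 3.44). Of 11 germ plasm genes 6 were higher in E, with dnd1 at 2.89 ± 0.23 and hook2 at 2.76 ± 0.22. Vegetal oocyte RNAs again had 8 of 10 higher in E and 1 lower, and animal pole RNAs 6 of 7 higher in A, led by exd2 (-3.33 ± 0.29). The camera adjusted p was 7.42e-06, 1.77e-10 and 7.42e-06, and with an estimated correlation the adjusted p was 0.25, 0.123 and 0.123. DNA replication had 4 of 26 higher in A (0.0275 by camera, adjusted p = 0.123 with an estimated correlation), with pola1 at -0.71 ± 0.13. Of 4 enveloping layer genes, grhl3 (55 counts in A and 0 in E) and gata3 (100 and 2 counts) were higher in A, and ppl did not pass (camera adjusted p = 0.345).

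The localisations of the 3 stages overlapped. Among 12548 genes tested in all stages, 516 were higher in E and 366 higher in A at each of them. Of the genes higher in E, 543 were shared by 1 and 2 hpf and 667 by 1 and 3 hpf, where independent lists would share 43.6 and 69.2.

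The study's title concerns the redistribution of RNA, which the change of the E-to-A difference between stages addresses. The centrosome gene pcnt had its higher mean in E at 1 hpf and in A at 3 hpf. At 1 hpf it stood at 392 ± 273 CPM in A and 1053 ± 480 CPM in E, and at 3 hpf at 1120 ± 62.0 CPM in A and 112 ± 55.6 CPM in E (SD, n = 3). Its E-to-A difference changed by -4.80 ± 0.50 (log2, SE; edgeR adjusted p = 4.52e-07). That result tests the change and not the difference at 1 hpf, where the values of both sections were widely spread. The gene lrmp did not differ detectably between A and E at 1 hpf (332 ± 52.4 and 343 ± 90.5 CPM) and stood at 450 ± 29.7 and 35.6 ± 13.1 CPM at 3 hpf, a change of -3.68 ± 0.38. For klf17 the change was -5.77 ± 1.15, but klf17 had only 70 counts over the 15 libraries of 1 hpf, against 1932 at 3 hpf. Its change therefore need not be a move of RNA present at 1 hpf. Smaller shifts toward A were those of pir (-2.13 ± 0.53), zdhhc24_2 (-2.07 ± 0.48) and the DNA repair gene dna2_1 (-1.34 ± 0.32). Toward E shifted rnaset2 (1.64 ± 0.33), a ribonuclease gene, the amino acid transporter slc7a3a (1.32 ± 0.30), the phospholipid enzyme ptdss2 (1.24 ± 0.25), eml3 (1.11 ± 0.21), dda1_1 (1.09 ± 0.25) and micall2a (1.09 ± 0.24).

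In all, 88 of 12668 genes changed from 1 to 3 hpf, 41 toward E and 47 toward A, and with library totals 36 and 85. From 1 to 2 hpf 3 genes changed, all toward A: pcnt (-3.08 ± 0.53), lrmp (-1.99 ± 0.38) and the centrosome gene cep350 (-0.79 ± 0.12). From 2 to 3 hpf 3 genes changed, among them the centrin gene cetn3 (-1.04 ± 0.19), toward A. Without section A of 1 hpf replicate 1 the change from 1 to 2 hpf was -2.84 for pcnt (edgeR adjusted p = 0.0938) and -1.94 for lrmp (0.207), and without section E of 2 hpf replicate 2 it was -0.64 for cep350 (edgeR adjusted p = 0.146). Over all alternatives the adjusted p of these changes ran from 0.00163 to 0.574 for pcnt, 0.011 to 0.574 for lrmp, 1.51e-06 to 1 for cep350 and 0.00319 to 0.826 for cetn3. The unadjusted counts under 0.05 were 1387, 1014 and 1332. These counts of 3 were 76 and 83 with DESeq2, 12 and 0 without replicate 3, and 0 and 0 without the embryo block. Without replicate 1 or 2 a single 2 hpf sample is left, so counts from those fits are not given for these 2 steps. The count of 88 was 15 without the embryo block, 165 with DESeq2, 32 without section A of 1 hpf replicate 1, and 29, 35 and 15 without replicate 1, 2 or 3. It was 121 without sections C and D of 2 hpf replicate 2 and 95 without its section E. Of the lists, first zygotic genes had a camera adjusted p of 5.66e-05 for this change, with 1 of 13 members called, and an adjusted p of 0.519 with an estimated correlation. Only 4 of the 13 passed the count filter at 1 hpf. For the others the change cannot be told apart from the appearance of the RNA.

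**Figure D4:**
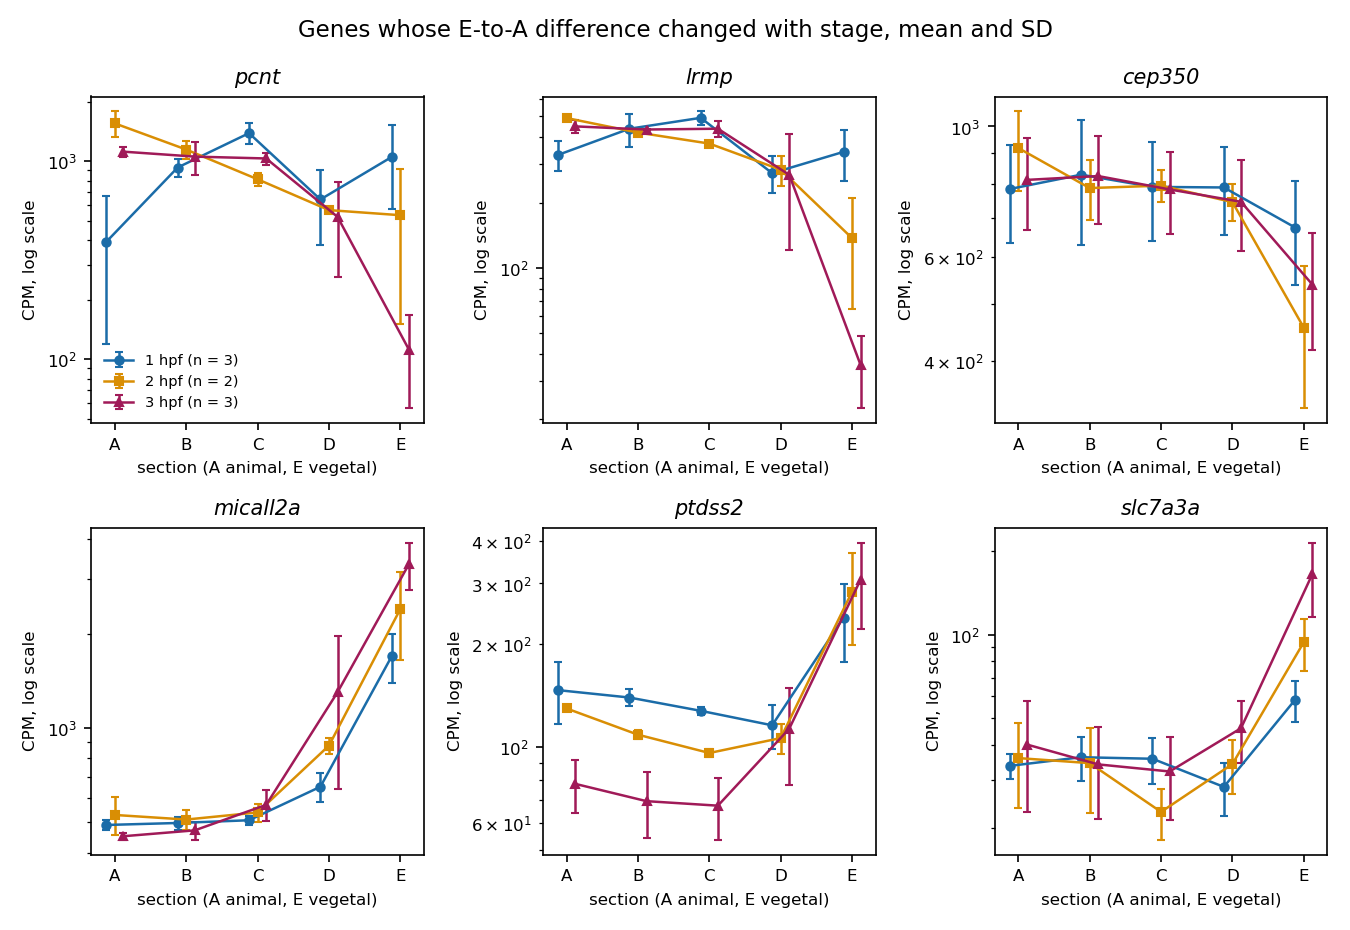
Mean CPM (log axis) with SD by section at 1, 2 and 3 hpf (n = 3, 2 and 3) for pcnt, lrmp and cep350, whose E-to-A difference shifted toward A, and micall2a, ptdss2 and slc7a3a, where it shifted toward E. In section E, pcnt had 1053 CPM at 1 hpf and 112 CPM at 3 hpf.

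Stages were compared on the summed sections to ask which transcripts appeared or were lost. From 1 to 3 hpf the miR-430 precursors went from 0 counts to 1387 (dre-mir-430a-2), 775 (dre-mir-430a-13) and 624 (dre-mir-430a-4), at least 615-fold, 344-fold and 277-fold higher. For vox the counts were 1 and 1026. The gene klf17 rose from 0.948 ± 0.266 to 33.8 ± 17.4 CPM (SD, n = 3; log2 fold change 5.15 ± 0.44 SE; edgeR adjusted p = 0.00946). Among transcripts that fell, commd6 went from 10.5 ± 1.18 to 1.35 ± 0.046 CPM (-2.96 ± 0.19), pef1, a calcium-binding protein gene, from 34.6 ± 2.35 to 4.55 ± 0.767 CPM (-2.92 ± 0.15), gbgt1l1 from 58.9 ± 1.59 to 10.9 ± 2.59 CPM (-2.43 ± 0.17) and the growth factor gene hbegfa from 114 ± 41.1 to 29.9 ± 7.80 CPM (-1.94 ± 0.30). These values of 1 stage lay beyond all 3 of the other.

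Of 12667 genes, 48 were higher and 173 lower at 3 than at 1 hpf with edgeR. With the replicate block there were 228 and 572, which include all 221 calls made without it. Of 13 first zygotic genes, 5 rose and 0 fell (10 and 0 over the list alone), among them irx7, gadd45bb and klf17, and 10 rose with the block. The camera adjusted p was 1.63e-16, 9.9e-12 with the block, and the adjusted p was 0.135 with an estimated correlation. Only 13 of the 34 listed first zygotic genes were in the count table, where every gene has at least 60 counts. Members with few earlier counts, such as vox with 1 at 1 hpf and 3 at 2 hpf, could enter only through 3 hpf. Their rise was fixed by that filter, so these values do not test whether first zygotic genes as a kind rose. Of 16 listed enveloping layer genes 4 were in the count table, and of these grhl3 and gata3 rose (camera adjusted p = 0.00254, 0.017 with the block, and 0.135 with an estimated correlation). The same limit holds for both. At 1, 2 and 3 hpf grhl3 had 3, 2 and 308 counts, and gata3 had 7, 13 and 556. Of 11 germ plasm genes 1 fell, ca15b (-0.88 ± 0.14; 5 over the list alone; camera adjusted p = 0.0187, and 0.45 with an estimated correlation), and with the block 1 rose and 3 fell (camera adjusted p = 0.0336). Section E weighed less in the 3 hpf sums, so a fall of RNAs high in E can come from depth alone. With equal weight of sections, and limma in place of edgeR, 185 of the 221 calls were kept. Single members of other lists were the cyclin gene ccnb2 (0.25 ± 0.05), the egg coat gene zp3b (-0.50 ± 0.09) and the replication genes ticrr (-0.38 ± 0.07) and mcm5 (-0.28 ± 0.05). Of the fixed genes, dazl (0.04 ± 0.14), buc (-0.12 ± 0.08), nanos3 (-0.61 ± 0.16), ddx4 (-0.18 ± 0.06), pou5f3 (0.07 ± 0.11) and nanog (0.19 ± 0.05) did not pass. The 48 and 173 genes became 0 and 5 without 1 hpf replicate 1, 0 and 6 without 1 hpf replicate 2, 13 and 65 without 1 hpf replicate 3, 1 and 6 without 3 hpf replicate 1, and 8 and 55 without 3 hpf replicate 3. Without either 2 hpf replicate they were 18 and 53, and DESeq2 gave 333 and 573.

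From 2 to 3 hpf, klf17 rose from 0.536 ± 0.021 CPM (n = 2) to 33.8 ± 17.4 CPM (n = 3; log2 fold change 5.96 ± 0.55; edgeR adjusted p = 0.031), and the histone gene hist1h2a2 rose by 0.59 ± 0.07. The genes pef1 (-1.93 ± 0.16), gbgt1l1 (-1.77 ± 0.18), cobll1a (-1.01 ± 0.12), atp6v0b (-0.98 ± 0.11), acsbg2 (-0.76 ± 0.07) and arl6ip1 (-0.75 ± 0.07) fell. In all 6 genes rose and 7 fell with edgeR, 1387 passed at an unadjusted p under 0.05, and DESeq2 gave 212 and 260. Leaving out any single embryo sample other than 3 hpf replicate 2 left at most 1 gene in each direction. First zygotic genes had 1 of 13 called (11 over the list alone; camera adjusted p = 3.06e-19, and 0.106 with an estimated correlation). As for 3 against 1 hpf, members of this list and of the enveloping layer list with few earlier counts are in the table only through 3 hpf. From 1 to 2 hpf edgeR called 0 genes in either direction (402 at an unadjusted p under 0.05), and DESeq2 called 1 higher and 23 lower. The sum of 2 hpf replicate 2 joins its sections C and D with sections A, B and E of another profile. The low counts of the comparisons with 2 hpf therefore do not show that little changed. Between 1 and 2 hpf, ribosomal proteins had a camera adjusted p of 1.71e-16 with a median of -0.23 and 0 of 68 members called, and an adjusted p of 0.548 with an estimated correlation. Vegetal oocyte RNAs had a camera adjusted p of 0.000509 for this step with a median of 0.25 and 0 of 10 members called, and an adjusted p of 0.548 with an estimated correlation. From 2 to 3 hpf camera also called ribosomal proteins (median 0.12, adjusted p = 4.62e-06), enveloping layer genes (2.60, 0.000797), maternal regulators (0.15, 0.0143), Nodal and BMP signalling genes (0.09, 0.0143), the piRNA pathway (-0.16, 0.0236) and animal pole RNAs (0.14, 0.0251), each with 0 called members. With an estimated correlation their adjusted p was 0.478, 0.111, 0.323, 0.242, 0.441 and 0.441. From 1 to 3 hpf it also called Nodal and BMP signalling genes (0.09, 0.0232), oocyte and egg coat genes (-0.19, 0.0232), the piRNA pathway (-0.16, 0.0278) and maternal regulators (0.11, 0.0325), with an adjusted p of 0.299, 0.378, 0.378 and 0.378 with an estimated correlation. With the replicate block their camera adjusted p was 0.0392, 0.0336, 0.025 and 0.0597.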

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

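The test of the change between stages, the splits of the samples and the test on summed counts for section E were chosen before their results were seen, and every other test in this part was chosen afterwards. The values that follow were singled out because the E-to-A difference itself differed between stages. There were 3 such genes for 2 against 1 hpf, 3 for 3 against 2 hpf and 88 for 3 against 1 hpf. From 1 to 2 hpf the log2 change was -3.08 for pcnt, -1.99 for lrmp and -0.79 for cep350. From 2 to 3 hpf it was -1.04 for cetn3. From 1 to 3 hpf it was positive for rnaset2 (1.64), slc7a3a (1.32), ptdss2 (1.24), eml3 (1.11), dda1_1 (1.09) and micall2a (1.09). It was negative for klf17 (-5.77), pcnt (-4.80), lrmp (-3.68), pir (-2.13), zdhhc24_2 (-2.07), dna2_1 (-1.34) and cldnd (-0.71).

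Section letters were exchanged at random within each replicate, 100 drawings per stage with the real one included. At 1 hpf 1 drawing gave as many genes differing among sections as the real 1451 (highest other 1254), 2 gave as many higher in E as the real 851 (highest other 867) and 1 gave as many higher in A as the real 799 (highest other 753). The drawing with 867 kept the letter E on the 3 E libraries and put A on libraries of A, B or C. At 3 hpf 1 of 100 drawings reached the real 1514, 1023 and 946, with 1135, 819 and 768 as the highest others. Chance is excluded for these 6 counts at the 0.05 level. For 3 against 1 hpf the 6 embryo samples allow 10 splits, too few for a share under 0.05. The real split, 1 of them, gave 48 higher and 173 lower genes, with 0 as the highest other in both, and 88 changes of the E-to-A difference, with 1 as the highest other. The 3 other splits that part all 3 replicate pairs gave 0 genes.

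Replicate 3 of 1 and 3 hpf stood apart from replicates 1 and 2. Depth is argued against as the whole cause, since 7 of its 10 libraries lay within the depth range of the other replicates. A candidate explanation is that reads of a parental variant were counted on other copies of a symbol: 60 symbols had rows that moved in opposite directions by more than 1 log2 unit, against a median of 18 and a highest value of 30 in 1000 random pairings. Symbols with several rows held 39.3% of the 450 genes that differed by more than 2 log2 units, against 12.2% of all genes. Genes with a single row were not tested, and different parents of the embryos, a biological difference, stay open.

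In 2 hpf replicate 2, sections C and D stood apart from A, B and E. The share of counts on the replicate 3 row was at most 16.4% in C and D, within the 6.23% to 18.1% of replicates 1 and 2, and 71.3% to 77.6% in A, B and E, within the 70.6% to 80.2% of replicate 3; this is in line with embryos of other parents in C and D. A mixture of both kinds within each section is argued against, since 0 of the 5 sections lay between those ranges. Position along the axis alone is argued against for these symbols, on 1 embryo sample. All 5 sections of 2 hpf replicate 1, which was not used to pick the symbols, lay at 12.5% to 15.7%. Of the 30 libraries of 1 and 3 hpf, 0 lay apart from the rest of their replicate. Both the symbols and the ranges were taken from those libraries, so that count by itself decides nothing. An exchange of sections with the third replicate of 2 hpf, which is not analysed here, stays open and was not tested.

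The 48 genes higher at 3 than at 1 hpf had a median change of the E-to-A difference of -3.974 (fitted log2) against -0.248 to 0.3 in 10000 random lists, and -2.482 with group counts under 3 set to 3. The change was below 0 in 35 of them, and at 3 hpf 23 were higher in A and 7 higher in E. Some of the 48 genes had almost no counts at 1 hpf, such as vox with 1 and dre-mir-430a-2 with 0 over 15 libraries. Their E-to-A difference at 1 hpf was not measurable, so the comparison with random lists does not by itself show a change of position. By its own rule the planned test of lower depth in E came out for depth, since the summed counts of the 48 genes were 35656 (35282 to 36069 in 100 drawings) in section A thinned to the depth of E and 54624 in E. Depth alone would give equal sums, and the sum holds genes higher in E, with map3k1 (16.5%), ccnb2 (12.7%) and cirbpb (11.6%) making up 40.8% of it, so it neither supports nor excludes depth. A gene by gene test chosen after this outcome found 23 of 23 genes below every drawing, but it ran on genes already called lower in E and decides nothing. A further test over all 48 genes, chosen last, found 33 below every drawing of thinned A and 8 above every drawing, against a median of 21 and a highest value of 32 in 1000 random lists matched on counts. This argues against depth as the whole cause, by a margin of 1 gene over the highest random list. Transcription in the cells above the yolk by 3 hpf stays open as a hypothesis.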

How the results depend on the processing

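Leaving out single libraries and summing the rows of a symbol were chosen after seeing the data. Of 234 comparisons of the 18 counts, 151 stayed within 1.5 times and 83 moved. Of 2649 for 226 named gene results, 2302 kept their call, 339 lost it, 8 gained it and 0 changed sign. Of 326 for 33 gene list results, 260 kept the call and 66 lost it. RLE size factors and no filter on low counts moved 0 of the 18 counts. The cause was not tested.

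Library totals gave 1699, 1003 and 2346 genes higher in A at 1, 2 and 3 hpf. No replicate block within stages gave 796 genes among sections, 566 higher in E and 414 higher in A at 1 hpf, and 849 among sections and 458 higher in A at 3 hpf. With all 40 libraries in 1 fit 2067 genes differed among sections at 2 hpf. Without section E of 2 hpf replicate 2 the 3 counts at 2 hpf were 521, 428 and 314. Leaving out a replicate gave 480 to 761 genes higher in A at 1 hpf and 953 to 1086 among sections at 3 hpf. It gave 850 to 3091 among sections at 2 hpf, where the lone sample left is assumed to vary like the other stages.

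For changes of the E-to-A difference (2 against 1, 3 against 2 and 3 against 1 hpf), DESeq2 gave 76, 83 and 165 and no replicate block 0, 0 and 15. Leaving out a replicate gave 2 to 67, 0 to 82 and 15 to 35. For 3 against 2 hpf the count was 5 with copies summed, 22 without sections C and D of 2 hpf replicate 2, 8 without its section E and 16 without section E of 3 hpf replicate 1. Without section A of 1 hpf replicate 1 it was 1 for 2 against 1 hpf and 32 for 3 against 1 hpf.

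For stages (higher and lower), DESeq2 gave 1 and 23 for 2 against 1 hpf, 212 and 260 for 3 against 2 hpf, and 333 and 573 for 3 against 1 hpf. The replicate block gave 45 and 11, 161 and 414, and 228 and 572. The 2 hpf samples share only a number with the others, with correlations of 0.0226 and -0.0278 for the 2 pairs. For 3 against 2 hpf, equal weight of sections gave 23 higher and the deposited totals 3 lower, both with limma in place of edgeR. Summed copies gave 16 and 14. For 3 against 1 hpf, again with limma, equal weight gave 82 higher and the deposited totals 79. Leaving out a replicate gave 0 to 65 higher and 5 to 221 lower for 3 against 1 hpf, and 0 to 5 and 0 to 13 for 3 against 2 hpf. No gene list call held with an estimated correlation. Section E was the shallowest at 3 hpf, at 1355607 to 2327972 counts.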

Other observations

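Other groups at 3 hpf showed members at either end. The Wnt mediator lef1 stood at 515 ± 54.6 CPM in section E and 23.4 ± 8.51 CPM in A (SD, n = 3; log2 fold change 4.55 ± 0.22 SE; edgeR adjusted p = 1.28e-12), whereas axin1, a scaffold of the destruction complex, was higher in A (-1.89 ± 0.16), as were the receptor genes fzd7b (-1.41 ± 0.14) and lrp5 (-0.96 ± 0.13). In all 3 of 15 Wnt genes were higher in E and 4 in A (camera adjusted p = 0.476). The T-box gene eomesa was higher in E (1.37 ± 0.16) and smad5 higher in A (-0.59 ± 0.10). Of 68 ribosomal protein genes 6 were higher in E at 3 hpf, among them rpl17 (0.74 ± 0.18), with a camera adjusted p of 0.397.

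In the piRNA pathway list 2 of 11 genes were higher in E and 5 in A at 3 hpf, with tdrkh_1 at 1.18 ± 0.26, tdrd1 at -1.46 ± 0.17, henmt1 at -1.83 ± 0.35 and piwil2 at -1.14 ± 0.15 (camera adjusted p = 0.0639). Of 13 oocyte and egg coat genes 2 were higher in E at 3 hpf and 1 in A (camera adjusted p = 0.48). The growth factor gene gdf9 was higher in E (0.97 ± 0.17).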
